A study of Arabidopsis thaliana with 20 samples.

How the data were processed

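Small RNA sequencing was done on Arabidopsis thaliana plants (ecotype Columbia, whole plants at 3 weeks) that carry hairpin RNA transgenes. A hairpin RNA folds back into a double-stranded stem, which Dicer-like enzymes cut into small interfering RNAs (siRNAs) of both strands. The labels name 20 samples. Read tables were used for 15 of them, all with a hairpin against EIN2, and the 5 samples with a hairpin against the reporter gene GUS were not analysed here, so the planned comparison of GUS hairpin structures, including the one with 1 mismatch in every 4 bases, was not made.

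The deposited values are raw read counts per library, strand and length from 18 to 25 nt, per the file headers. Per the submitters' processing notes, cutadapt and Bowtie 1.0 were used and TAIR10 was the genome build. Per the file headers, reads were counted on a WT stem (the perfectly paired sequence) and on a GU stem (the sequence altered to form G:U pairs). For WT hairpin libraries only the WT stem was filled in. The mismatches allowed, the treatment of reads that fit both stems and any filter on reads are not given in the sources used here. The tables held no library totals, so counts could not be scaled to depth and the abundance of siRNAs was not compared between libraries. A size share within a library does not depend on the library total.

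The reads came from 2 tables, a first with 4 libraries and a second with 11, named as separate batches by the submitters. The second listed 4 entries for each library under a column headed replicate. They were taken here as repeat runs of 1 library. Over the size, strand and stem classes with at least 20 reads, the runs of a library differed by no more than sampling noise in a chi-square test of their read counts (lowest unadjusted p = 0.0101 in 11 libraries, Benjamini-Hochberg adjusted p = 0.111). They were summed and counted as 1 replicate. Of the 11 libraries, 1 had an unadjusted p under 0.05.

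Groups were taken from sample titles. The genotype label of the 2 samples titled as ocp11 plants with the G:U hairpin says WT hairpin. The title was followed, and the tables list reads on the GU stem for both. A library of nrpd1a plants with the WT hairpin has the number 13 in the table and 3 in its title. It was used as the remaining library of that group. For 3 samples the label names a target gene other than EIN2, and for these the title was followed too. The labels do not say whether the libraries of a group came from separate plants or pools, so p-values measure the spread between these libraries only. Groups held 1 or 2 libraries.

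For each library the sense siRNAs were the sense reads on the stem that the hairpin carries (the GU stem in G:U plants), and the antisense siRNAs were the antisense reads on the WT stem. The labels do not say which strand of the G:U hairpin was altered, and this choice followed the tables: in G:U libraries a median of 0.555% of sense reads lay on the WT stem and 0.319% of antisense reads on the GU stem. Summing both stems was an alternative. Shares were taken over lengths of 20 to 24 nt. The 7 measures were the 21-nt, 22-nt and 24-nt shares of antisense and of sense siRNAs and the antisense share of both strands. They were compared with exact stratified permutation tests, two-sided, of the mean over strata of the difference in group means, with Benjamini-Hochberg adjustment over the 7 measures and a threshold of 0.05. The comparison of hairpins permuted labels within the first table's Columbia, nrpd1a and ocp11 backgrounds (smallest p of this exact test 0.00926). The comparison of backgrounds permuted labels within each hairpin. For a single mutant this gives 18 arrangements and a smallest p of 0.0556, so it cannot pass the threshold, and for both mutants together 75 arrangements and 0.0133. The measures, tests, strata, named size classes and most alternatives were fixed before the data were examined. The tables hold no genes. By the rule set in advance the 21-nt, 22-nt and 24-nt classes are given in full and the 20-nt and 23-nt classes as ranges. The test was checked on 300 simulated sets of libraries at the real depths with an SD of 5 percentage points between libraries. A true difference of -20 percentage points in the antisense share was estimated as -20.3 on average and had p under 0.05 in 100% of sets, and with no difference 4.67% of sets did. These p were unadjusted and the SD was the same for both hairpins. The real group SDs of the antisense share ran from 0.121 to 16.5. A single measure at the smallest p of the exact test adjusts to 0.0648 unless other measures have p low enough to lower it. The check therefore does not describe the adjusted calls.

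The 20 to 24 nt reads per library ranged from 11547 to 969784. The widest 95% Wilson interval of a size or strand share over 20 to 24 nt reached 1.28 percentage points to either side. Antisense shares by single length and size shares of reads on the other stem rest on fewer reads and have wider counting error. At 23 nt, nrpd1a WT library 3 had 116 antisense and 79 sense reads. No molecular identifiers are named in the sources used here, and intervals cover counting error only.

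The alternatives were all listed sizes as the denominator, both strands as the denominator, log2 odds with 0.5 added to each count, other sets of strata, same-numbered libraries averaged, reads summed over a group, other controls, single hairpins, the number as a block, and each library left out in turn. A minimum of 1000 reads per library removed 0 libraries and so changed nothing. Adding the GUS samples as a stratum was not run. Sums over both stems, each table alone, the 23-nt measures and a crossed pairing were chosen after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.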

Results

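Small RNAs of the hairpin stem were counted in 15 libraries of 3-week-old Arabidopsis plants that express a hairpin RNA against EIN2, a membrane protein required for ethylene signalling. EIN2 (AT5G03280) lies on chromosome 5 from 787428 to 793404 in the TAIR10.1 assembly. The part of the gene used as the stem is not given in the labels, so no siRNA position is reported. The hairpin was either perfectly paired (WT, 7 libraries) or carried G:U wobble pairs in the stem (G:U, 8 libraries). The first table held WT libraries 15 and 17 and G:U libraries 12 and 13 in Columbia. The second held WT library 15 and G:U libraries 12 and 13 in Col-0, and 2 libraries of each hairpin in each of the mutants nrpd1a and ocp11. The gene NRPD1a encodes the largest subunit of RNA polymerase IV, which starts the production of 24-nt siRNAs, and ocp11 is a mutant of ARGONAUTE4, which binds 24-nt siRNAs. In Arabidopsis, DCL4, DCL2 and DCL3 cut 21-nt, 22-nt and 24-nt siRNAs, respectively. No library without a hairpin transgene was used, so no background level of stem reads can be given.

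The raw counts of 20 to 24 nt stem reads ranged from 11547 in a WT hairpin library of nrpd1a to 969784 in a G:U hairpin library of ocp11. Library totals were not given, and these counts were not compared between libraries. The 21-nt class was the largest in all 30 combinations of library and strand. Reads of 18, 19 or 25 nt made up 4.52% to 14.7% of the stem reads of a library. Those of 18 or 19 nt made up more in each WT than in each G:U library of the same background and table. They were 14.4% and 10.4% against 7.69% and 4.83% in the first table and 6.96% against 4.94% and 5.84% in Col-0. In nrpd1a they were 7.01% and 7.91% against 4.51% and 5.44%, and in ocp11 7.19% and 6.25% against 4.82% and 4.18%. The cause was not tested.

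The study asked how the structure of a hairpin RNA changes its processing into small RNAs. Antisense siRNAs, the strand able to pair with EIN2 mRNA, formed a much smaller part of the stem siRNAs in G:U plants than in WT plants. In the first table the antisense share was 53.5% ± 16.5 (SD, n = 2) with the WT hairpin and 15.2% ± 2.36 (SD, n = 2) with the G:U hairpin. It was 53.2% ± 1.64 and 21.2% ± 2.36 (SD, n = 2 each) in nrpd1a, and 46.6% ± 0.121 and 20.3% ± 1.37 (SD, n = 2 each) in ocp11. All 7 WT libraries lay between 41.9% and 66.8%, and all 8 G:U libraries between 13.6% and 22.9%. Put as a ratio, WT libraries had 0.721 to 2.01 antisense reads per sense read and G:U libraries had 0.157 to 0.296. The antisense share fell by 32.2 percentage points from WT to G:U, with an SD of 5.97 over the 3 backgrounds (exact stratified permutation test, two-sided, p = 0.00926, the smallest that this design can give, adjusted p = 0.0324). Within the first table alone the difference was -38.3 percentage points, and 2 against 2 libraries cannot go below p = 0.333 in an exact test. Within the second table, with the Col-0 libraries as a stratum, it was -35.1 percentage points (exact stratified permutation p = 0.00926, adjusted p = 0.0648). Without first-table G:U library 12, G:U library 13 or ocp11 WT library 10 the value was -32.8, -31.7 or -32.2 percentage points, and over all listed sizes it was -31.2, each with an adjusted p of 0.0648 in the exact test.

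**Figure D1:**
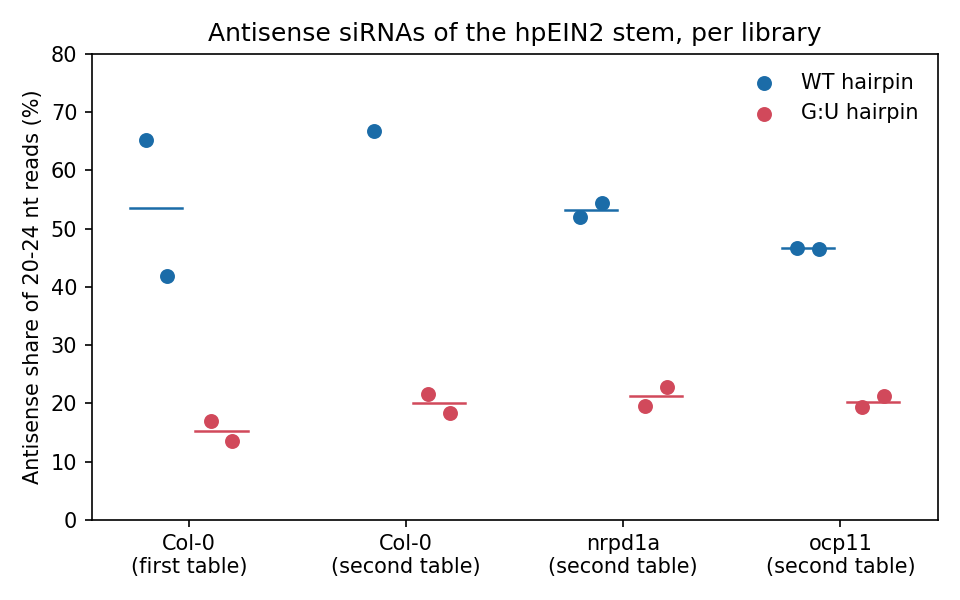
Antisense share of 20-24 nt stem reads (y axis, percent) in each library, by plant background and table (x axis). Points are libraries, blue for the WT and red for the G:U hairpin, and short lines are means of 2 libraries. WT libraries lie between 41.9% and 66.8% and G:U libraries between 13.6% and 22.9%.

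The size profile of antisense siRNAs also differed between the hairpins. The 21-nt class held 72.6% ± 13.7 of antisense siRNAs in WT plants and 52.1% ± 5.05 in G:U plants of the first table (SD, n = 2 each). It held 73.6% ± 0.576 and 50.2% ± 1.16 in nrpd1a, and 61.2% ± 4.11 and 49.7% ± 11.0 in ocp11 (SD, n = 2 each). The 21-nt antisense share fell by 18.5 percentage points over the 3 backgrounds (exact stratified permutation test, two-sided, p = 0.00926, adjusted p = 0.0324). This call did not hold within the second table with its Col-0 libraries, where the difference was -9.44 percentage points (exact stratified permutation p = 0.130), nor without first-table G:U library 12, G:U library 13 or ocp11 WT library 10 (-17.3, -19.6 and -17.5 percentage points, adjusted p of the exact test 0.0648, 0.0864 and 0.0648). It also ended over all listed sizes (-16.2) and with the Col-0 libraries as a further stratum (-12.2), with adjusted p of 0.0648 and 0.0720 in the exact test. In those Col-0 libraries the 21-nt antisense share was 44.7% (95% Wilson interval 44.5 to 44.9) in the WT library and 51.2% ± 0.907 (SD, n = 2) in the G:U libraries, the opposite order.

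The 24-nt class of antisense siRNAs had a mean of 15.6% with the G:U hairpin and 11.4% with the WT hairpin over the 3 backgrounds, a difference of 4.23 percentage points that did not pass the threshold (exact stratified permutation p = 0.0370, adjusted p = 0.0648). It passed without ocp11 WT library 11 (5.25, exact test adjusted p = 0.0324), while the difference was -2.56 percentage points within the second table and 2.41 with same-numbered libraries averaged. The order was opposite in the Col-0 libraries of the second table, at 12.6% ± 0.834 (SD, n = 2) against 27.2% (95% Wilson interval 27.0 to 27.4) in the WT library. The 22-nt class, cut by DCL2, was small with either hairpin. Its antisense share was 7.48% with the G:U and 5.90% with the WT hairpin, a difference of 1.58 percentage points (exact stratified permutation p = 0.130, adjusted p = 0.181). It was 0.895 without WT library 15 of the first batch, 0.711 within the second table and 2.96 without the ocp11 background. The 23-nt class, given as a range by the rule set in advance, held 8.94% to 26.3% of antisense siRNAs in the 8 G:U libraries and 1.54% to 9.34% in the 7 WT libraries. The 20-nt class held 5.88% to 14.6% and 8.32% to 16.6%, respectively.

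None of the 3 sense size classes tested passed the threshold. The 21-nt sense share was 56.5% with the G:U and 56.8% with the WT hairpin, averaged over the 3 backgrounds (exact stratified permutation p = 0.963). The 24-nt sense share was 19.97% and 15.6%, a difference of 4.40 percentage points (exact stratified permutation p = 0.157, adjusted p = 0.184). It was higher with the G:U hairpin in the first table by 6.18 and in nrpd1a by 9.14 percentage points, while in ocp11 the difference was -2.13. The mean was 2.88 percentage points without ocp11 WT library 10 and 7.66 without the ocp11 background. The 22-nt sense share was 8.28% and 9.85%, a difference of -1.57 percentage points (exact stratified permutation p = 0.0278, adjusted p = 0.0648). It passed without ocp11 WT library 11 or ocp11 G:U library 6 (-1.60 and -1.81, exact test adjusted p = 0.0486 and 0.0324), and with the Col-0 libraries as a further stratum (-2.39, exact test adjusted p = 0.0162), and was -0.876 over all listed sizes. As shares of both strands, the 22-nt and 24-nt antisense classes were lower with the G:U hairpin (-1.51 and -2.53 percentage points) and the 21-nt, 22-nt and 24-nt sense classes higher (18.3, 1.96 and 8.18), with adjusted p of 0.0130 to 0.0185 in the exact test. This denominator takes the antisense share, which differed by -32.2 percentage points, into each class. These passes therefore largely restate that difference. Within the sense strand the 21-nt share differed by -0.258 percentage points. Sense siRNAs of 23 nt made up 2.66% to 5.34% in G:U libraries and 1.50% to 5.46% in WT libraries, and those of 20 nt 9.31% to 16.8% and 8.63% to 24.7%.

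**Figure D2:**
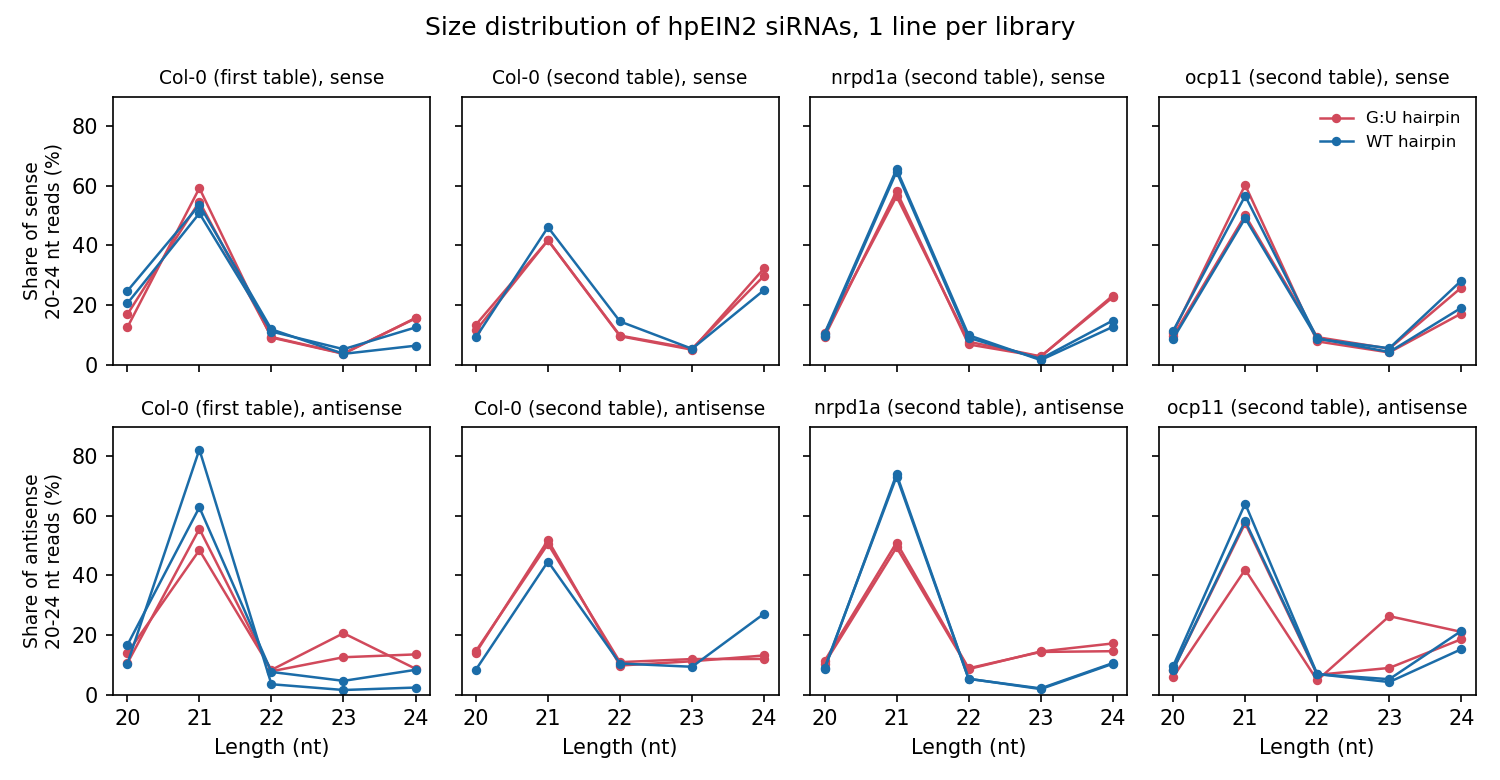
Share of each length (x axis, nt) among sense (top panels) and antisense (bottom panels) 20-24 nt stem reads (y axis, percent), by background and table (columns of panels), with 1 line per library, blue for the WT and red for the G:U hairpin. The 21-nt class is the largest in all 30 profiles, and the 23-nt antisense class reaches 8.94% to 26.3% in G:U libraries.

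The mutant libraries bear on whether the size and strand profile of hairpin siRNAs depends on the pathway of RNA polymerase IV and ARGONAUTE4. The titles give them other numbers than the Col-0 libraries. If the numbers mark transgene lines, a difference of background cannot be told apart from a difference between lines. Within 1 genotype, first-table WT libraries 15 and 17 had antisense shares of 65.2% and 41.9% and 21-nt antisense shares of 82.3% and 62.9%. Sense siRNAs of 24 nt were less frequent in nrpd1a than in the Col-0 libraries of the same table with both hairpins. With the WT hairpin the 24-nt sense share was 13.7% ± 1.50 (SD, n = 2) in nrpd1a and 25.04% (95% Wilson interval 24.8 to 25.3) in the 1 Col-0 library. With the G:U hairpin it was 22.8% ± 0.395 in nrpd1a and 31.1% ± 1.77 in Col-0 (SD, n = 2 each). The mean difference was -9.78 percentage points (exact stratified permutation p = 0.0556, the smallest that this design can give, adjusted p = 0.0972). With the first table's Columbia libraries added to the controls it was -0.688 percentage points (exact stratified permutation p = 0.933). Those first-table libraries alone had 24-nt sense shares of 9.39% ± 4.34 (WT) and 15.6% ± 0.0967 (G:U) (SD, n = 2 each). These lay below the nrpd1a means with both hairpins, so the direction depended on which Columbia libraries served as control. All mutant libraries are from the second table, so tests with these added controls ignore the table and take in the numbers 15, 12 and 13 from both tables. As shares of both strands the difference was -4.36 percentage points (exact stratified permutation p = 0.111). The class was still well above 0 in every nrpd1a library, with a lowest share of 12.6%. In ocp11 the 24-nt sense share was 23.6% ± 6.45 with the WT and 21.5% ± 6.15 with the G:U hairpin (SD, n = 2 each), a mean difference from Col-0 of -5.50 percentage points (exact stratified permutation p = 0.278), or 3.59 with the added controls and -1.73 as shares of both strands. It was -1.42 with the WT hairpin alone, -3.22 without ocp11 WT library 10, -3.33 without ocp11 G:U library 4 and -9.59 without the Col-0 WT library.

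In antisense siRNAs of 24 nt, Col-0 lay above both mutants with the WT hairpin and below both with the G:U hairpin. With the WT hairpin their share was 27.2% in the Col-0 library, 10.5% ± 0.162 in nrpd1a and 18.3% ± 4.33 in ocp11 (SD, n = 2 each for the mutants). With the G:U hairpin it was 12.6% ± 0.834 in Col-0, 15.9% ± 1.84 in nrpd1a and 19.8% ± 1.74 in ocp11 (SD, n = 2 each). Averaged over the hairpins, the difference from Col-0 was -6.70 percentage points in nrpd1a (exact stratified permutation p = 0.333) and -0.799 in ocp11 (exact stratified permutation p = 0.889). Without the Col-0 WT library these were 3.32 and 7.27, with the added controls 0.945 and 6.85, and as shares of both strands -5.89 and -4.05 percentage points. The G:U difference exceeded the WT difference by 18.1 percentage points for both mutants together. It had p = 0.0133 (exact permutation of backgrounds within hairpins, the smallest possible, adjusted p = 0.0933) and did not pass the threshold after adjustment. A single measure at this smallest p passes only when other measures have low p too, and here the next lowest exact permutation p was 0.0667 (antisense share). With the first table's Columbia libraries added to the controls it was 4.27 percentage points (exact permutation p = 0.568). This value cannot be formed without the single Col-0 library with the WT hairpin. Between the mutants, the 24-nt antisense share was 5.90 percentage points lower in nrpd1a than in ocp11 (difference -5.90, exact stratified permutation p = 0.0556, the smallest possible, adjusted p = 0.292). As shares of both strands the difference was -1.83 percentage points.

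With both mutants as 1 group against Col-0, 3 of the 7 measures passed the threshold. The 21-nt sense share rose by 13.7 percentage points, by 12.9 with the WT and by 14.5 with the G:U hairpin. The 22-nt share fell by 3.74 percentage points among antisense and by 3.59 among sense siRNAs. Each of these 3 had p = 0.0133, the smallest that the exact stratified permutation test can give, and adjusted p = 0.0311. As shares of both strands the differences were 12.6, -2.26 and -0.882 percentage points, and the 3 calls ended (adjusted p = 0.0622 in the exact test). The 24-nt sense share differed by -7.64 percentage points and did not pass (exact stratified permutation p = 0.0667, adjusted p = 0.117), except without ocp11 WT library 11 (-9.23, exact test adjusted p = 0.0292). Neither did the antisense share, at -8.06 (exact stratified permutation p = 0.147, adjusted p = 0.171), nor the 21-nt and 24-nt antisense shares, at 10.7 and -3.75 percentage points (exact stratified permutation p = 0.133 and 0.480). With the first table's Columbia libraries added to the controls, these 4 differences were 1.45, -2.45, 1.24 and 3.90 percentage points. Without the Col-0 WT library the antisense share and the 21-nt and 24-nt antisense shares turned to 0.773, -1.23 and 5.30, and as shares of both strands the 24-nt sense and 21-nt antisense differences were -3.04 and 2.05. Without the single Col-0 library with the WT hairpin (number 15) the differences were 14.5, -3.13 and -1.77 percentage points for the 21-nt sense, 22-nt antisense and 22-nt sense shares, each with adjusted p = 0.187 in the exact test. No exact p of that set can go below 0.0667, so no call was possible. Leaving out Col-0 G:U library 12 or 13 or nrpd1a WT library 2 or 3 also ended these 3 calls, at values from 12.6 to 13.7, -4.02 to -3.46 and -3.72 to -3.54 and adjusted p from 0.0583 to 0.0933 in the exact test. With the first table's Columbia libraries added to the controls, which ignores the table, the differences were 7.89, -1.54 and -2.47 percentage points, and the first 2 of these calls ended. The second table's Col-0 libraries themselves differed from the same-numbered libraries of the first table in these measures. The mean differences were -12.6 (21-nt sense), 3.84 (22-nt antisense) and 1.18 (22-nt sense) percentage points.

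The numbers 15, 12 and 13 appear in titles of both tables, and the labels do not say whether they mark the same lines or plants. The second table's libraries had more 24-nt sense siRNAs at all 3 numbers, by 18.7 percentage points in WT library 15, 16.8 in G:U library 12 and 14.2 in G:U library 13. The mean difference of 16.6 percentage points had p = 0.100, the smallest that an exact permutation test of 3 against 3 can give, and as shares of both strands the mean was 9.80. For antisense siRNAs the 24-nt share moved by 24.8, 4.46 and -1.53 percentage points at the same numbers (mean 9.25, exact permutation p = 0.300), and the mean was 4.37 without the Col-0 WT library and 6.12 as shares of both strands. The antisense share of both strands moved by 1.64, 4.70 and 4.75 percentage points (mean 3.70, exact permutation p = 0.5). With single libraries left out the mean ranged from -11.9 to 20.3, and it was negative without second-table WT library 15 (-11.9) or first-table G:U library 12 (-3.80) or 13 (-5.46). Leaving out 1 library makes the hairpins unequal between the tables, so these left-out means also take in the difference between the hairpins. They do not measure how steady the shift between the tables was. The exact test did not keep the hairpins apart either.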

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

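The mutant difference in the 24-nt antisense share differed between the hairpins in value, but not past the threshold after adjustment. The G:U hairpin difference minus the WT hairpin difference was 20.04 percentage points for nrpd1a (exact permutation p = 0.0556), 16.1 for ocp11 (exact permutation p = 0.111) and 18.1 for both mutants together (exact permutation p = 0.0133, the smallest possible, adjusted p = 0.0933). All 3 values use the same single Col-0 library with the WT hairpin, and with the first table's Columbia libraries added to the controls the value for both mutants was 4.27 (exact permutation p = 0.568). The G:U minus WT difference also went opposite ways in the Columbia libraries of the tables. The second table minus the first was 27.0 percentage points for the 21-nt antisense share, -20.4 for the 24-nt antisense share and -9.16 for the 21-nt sense share, and these differences were not tested.

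Some reads lay on the stem that their strand was not assigned to. In the 8 G:U libraries a median of 0.555% of sense reads lay on the WT stem (0.0868% to 1.14%, 118 to 3269 reads), and a median of 0.319% of antisense reads lay on the GU stem (0.142% to 0.799%, 30 to 1660 reads). Whether these are wrongly mapped reads was not tested.

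At the same numbers the log2 ratio of 24-nt to 21-nt reads moved from the first table to the second by 2.20 (sense) and 4.41 (antisense) in WT library 15, by 1.45 and 0.50 in G:U library 12, and by 1.44 and -0.04 in G:U library 13, and no explanation was tested.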

How the results depend on the processing

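Values are percentage points, and sums of both stems, the single tables, the 23-nt class and the crossed numbers were chosen after seeing the data. For G:U minus WT, 113 of 146 alternative values with a test of the 7 measures kept their direction and side of the threshold after adjustment. For both mutants minus Col-0 90 of 125 did and for the interaction 15 of 15. Single mutants and the repeat cannot pass the threshold in their main design, and only directions were counted for them: 14 of 14 values kept their direction for nrpd1a minus ocp11, 25 of 28 for nrpd1a and 22 of 28 for ocp11 minus Col-0, and 32 of 35 for the repeat. The 23-nt antisense share has no adjusted p. Its unadjusted p in the exact test rose to 0.0556 over both strands or without the ocp11 stratum and to 0.333 in the first table. Reads summed over a group have no test. Controls from both tables ignore the table. Without the ocp11 stratum no p can go below 0.0556 and in the first table alone 0.333. Without G:U library 12 or 13 or ocp11 WT library 10 the antisense share kept p = 0.00926 in the exact test. Its adjusted p rose because the p of the 21-nt antisense share did (0.0278). Elsewhere the cause was not tested. The GUS stratum was not run, and the minimum of 1000 reads removed 0 libraries. Counting error alone reaches at most 1.28 percentage points for a share.

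For the hairpins, the antisense share kept its direction. It was -31.2 over all listed sizes, -35.2 without the ocp11 stratum, -38.3 in the first table, -35.1 in the second and -36.1 to -28.4 with each library left out. It lost its call in the first 4 of these and without G:U library 12 or 13 or ocp11 WT library 10. The 21-nt antisense share likewise lost its call over all listed sizes (-16.2), with Col-0 as a further stratum (-12.2), without the ocp11 stratum (-21.9) and in the first (-20.5) or second table (-9.44), with -21.7 to -15.2 when each library was left out. With both strands as denominator the 22-nt (-1.51) and 24-nt (-2.53) antisense and 21-nt (18.3) and 22-nt (1.96) sense shares reversed. The 24-nt sense share was 8.18, and all 5 passed (adjusted p of 0.0130 to 0.0185 in the exact test). The 24-nt antisense share also reversed with the Col-0 stratum (-0.483) and in the second table (-2.56), and ranged from 3.21 to 5.25 with each library left out, and was 2.41 with same-numbered libraries averaged. The 21-nt sense share, near 0, reversed over all listed sizes (2.93) and in the first table (4.79), and ranged from -1.95 to 1.44, reversed without WT library 15, G:U library 12, nrpd1a G:U library 18, ocp11 WT library 10 or ocp11 G:U library 6. The 22-nt sense share passed with the Col-0 stratum (-2.39), was -0.876 over all listed sizes and ranged from -1.81 to -1.33. The 22-nt antisense share ranged from 0.895 to 2.27 (2.96 without the ocp11 stratum) and the 24-nt sense share from 2.88 to 5.92.

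For both mutants the called 21-nt sense, 22-nt antisense and 22-nt sense shares kept their direction and lost their calls with both strands as denominator (12.6, -2.26 and -0.882), with the G:U hairpin alone (14.5, -3.13 and -1.77) and with the WT hairpin alone (12.9, -4.35 and -5.40). With the added Columbia controls the 21-nt sense (7.89) and 22-nt antisense (-1.54) calls ended and the 24-nt sense (1.45) and antisense (3.90) shares reversed. With the G:U hairpin alone the 21-nt antisense (-1.23), 24-nt antisense (5.30) and antisense share (0.773) reversed. With each library left out the ranges were 12.6 to 15.4 (21-nt sense), -4.02 to -3.13 (22-nt antisense), -3.81 to -1.77 (22-nt sense), -9.23 to -6.64 (24-nt sense), -1.23 to 12.3 (21-nt antisense), -4.91 to 5.30 (24-nt antisense) and -8.88 to 0.773 (antisense share). Reversals among these came without the Col-0 WT library.

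For nrpd1a minus Col-0 the 24-nt antisense share reversed with the G:U hairpin alone (3.32) and with the added controls (0.945), and ranged from -7.35 to 3.32, reversed without Col-0 WT library 15. The 24-nt sense share was -0.688 with the added controls. For ocp11 the 24-nt antisense share reversed as log2 odds (0.0140), with the G:U hairpin alone (7.27) and with the added controls (6.85), and ranged from -2.33 to 7.27, reversed without Col-0 WT library 15 (7.27) or ocp11 WT library 10 (0.733), while the 24-nt sense share reversed with the added controls (3.59), was -1.42 with the WT hairpin alone and ranged from -9.59 to -3.22. For nrpd1a minus ocp11 the 24-nt antisense share was -1.83 with both strands as denominator.

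Between the tables, 3 numbers are shared. The labels do not say that they mark the same lines, so a test without the number as a block was fixed in advance. Deviations of the 2 same-numbered G:U pairs correlated at -0.100 over the measures, which cannot show whether the libraries are paired. With the number as a replicate block the means stayed 16.6 (24-nt sense), 9.25 (24-nt antisense) and 3.70 (antisense share), no exact p can go below 0.25, and 0 of 7 measures passed with no block, the block or crossed G:U numbers. With each library left out the 24-nt antisense share ranged from 4.37 (without second-table WT library 15) to 11.98, and the antisense share from -11.9 to 20.3, reversed without second-table WT library 15 (-11.9) or first-table G:U library 12 (-3.80) or 13 (-5.46). With unequal hairpins in the tables, these means and reversals also take in the hairpin difference.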

Other observations

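The tests of the 23-nt class, the tests by length and the tests of explanations were chosen after the data were seen, while the test of the antisense share itself was fixed before. The antisense share was lower in G:U plants at 7 of the 8 listed lengths, by differences of -17.7 (19 nt) to -38.5 (21 nt) percentage points in the antisense share of reads of that length (exact stratified permutation, adjusted p = 0.0106 each). The exception was 23 nt, at 1.40 percentage points (exact stratified permutation p = 0.750), with 33.4% to 60.8% antisense in G:U and 39.2% to 78.1% in WT libraries. In the Col-0 libraries of the second table, which stood outside that test, the 23-nt difference was -42.3 percentage points. Sense reads on the WT stem of G:U libraries had a median 21-nt share of 58.5% and a median 24-nt share of 10.07% over the 8 libraries.

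The lower antisense share in G:U plants was set against 2 technical explanations. Antisense reads counted on the GU stem would have to be 77.7% of all antisense reads to bring the share to that of WT plants, and no G:U library had more than 0.799% there. The WT stem was chosen for antisense reads from these same percentages, so they are not an independent test. With both stems summed, which needs no such choice, the difference was -32.2 percentage points. A single abundant size class would leave the other lengths alike, and 7 size classes were lower past the threshold. These values argue against each as the whole cause. Fewer antisense siRNAs, more sense siRNAs, unequal adapter ligation of the strands, reads that match neither stem and a few abundant sequences all stay open, since the tables hold neither library totals nor sequences.

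The 23-nt share of antisense siRNAs was higher in G:U plants by 13.0 percentage points (16.2% against 3.24%, exact permutation p = 0.00926), by 9.20 within the second table and by 2.22 in its Col-0 libraries alone, and as a share of both strands by 1.54 (exact permutation p = 0.0556). Shortened 24-nt siRNAs as the whole cause would leave the 23-nt plus 24-nt share alike, and it differed by 17.2 percentage points over the 3 backgrounds (exact permutation p = 0.00926), but by -12.4 in the Col-0 libraries, where the small 23-nt difference leaves shortening open. A fall of the 21-nt class alone would leave the 23-nt share of the remaining antisense siRNAs alike, and it differed by 22.1 percentage points (exact permutation p = 0.00926) and by 6.81 in the Col-0 libraries. Without ocp11 G:U library 6, which had the highest share, the 23-nt difference was 10.06 percentage points (exact permutation p = 0.00926), against that library as the whole cause. The hairpin structure and a single abundant 23-nt sequence stay open and untested.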
